A study of Arabidopsis thaliana with 30 samples.

How the data were processed

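RNA sequencing was carried out on 7-day-old Arabidopsis thaliana seedlings of 5 genotypes, each with and without methyl methanesulfonate (MMS, a DNA-alkylating agent), with 3 replicates in each of 10 groups and 30 libraries in all. The growth protocol speaks of whole seedlings while the tissue field reads leaves, and the labels give neither the dose of MMS nor its duration. Libraries were sequenced as paired-end reads of 150 nt. Per the submitters' notes, the authors aligned reads with STAR to TAIR10 and normalised them with DESeq2 1.30.1. The authors deposited a table of normalized signal, that is reads per gene divided by a size factor for each library, and a table of FPKM, in which fragments are scaled by gene length and by the total over the listed genes. Every value of the first table was a whole multiple of the smallest step of its library (100% of values, tolerance 0.01 of a read), so the whole reads per gene could be recovered. The notes state neither the strand of the libraries nor how reads shared by overlapping or similar genes were counted, so values of such genes, histone genes among them, are uncertain. Both tables hold 20404 genes, of which 19933 are protein coding, and none is an organelle or transposable element gene. No gene has 0 reads in any library, so a filter was applied before deposition that the notes do not describe. Genes with no read in some libraries, transposable elements among them, are therefore not analysed here. All 20404 loci matched the TAIR10.1 annotation, which supplied symbols and positions. Positions below are in the TAIR10.1 annotation.

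The plan had assumed a table of whole counts and, as the main test, edgeR's quasi-likelihood test with TMM scaling. Because the deposited values are normalised, the comparisons were made with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend) on log2(normalized count + 1), and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads served as alternatives. Genes with a normalized count of at least 10 in at least 3 libraries were tested, which removed 148 genes and left 20256. A single model held all 30 libraries with a coefficient for each group and 20 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg (BH) method within each comparison and genes with an adjusted p under 0.05 were called. Fold changes are on the log2(value + 1) scale with their standard error (SE), and group levels are mean normalized counts ± SD with n = 3. The comparisons were each mutant against wild type (Col) without and with MMS, MMS against mock in each genotype, the difference of each mutant's MMS response from that of Col, the non-additive part of the double mutant (XW minus X minus W plus Col), and XW against tsk. Differences between MMS responses and non-additive effects are tests of an interaction term.

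The comparisons, the alternatives, 16 gene lists (272 genes, of which 247 are in the tables) and the rule for named genes were fixed before the data were examined. The lists cover the targeted genes, DNA damage response, homologous recombination and fork repair, base excision and alkylation repair, S phase and replication, G2/M cell cycle, meristem and stem cell, salicylic acid and immune, oxidative and xenobiotic stress, heat shock and protein folding, anthocyanin and flavonoid, leaf photosynthesis, root markers, circadian clock, silencing reporters and other H2A genes. Genes raised or lowered by MMS in both X and W formed a further pair of lists, tested in XW and tsk without MMS. A list was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Named genes are the targeted genes, up to 3 called members of each list with the smallest adjusted p, the 5 largest rises and falls among called genes with a mean of at least 1 CPM (counts scaled to library totals) and no overlap between the libraries of the groups, and the 5 rises and 5 falls shared by XW and tsk with the largest smaller change. For the single mutants, the comparisons with Col under MMS and XW against tsk under MMS the first 3 of each were used. The condition on overlap was not applied to interaction terms.

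Depth over the listed genes was 15343687 to 25115027 reads per library. The procedure was tested on simulated data made from the mean levels of the Col mock libraries and a spread per gene estimated over all libraries. In the libraries standing for tsk mock 200 genes were given a change. Each gene had the same spread in all groups, so a library lying apart from its group was not modelled. Of 67 genes changed by 1.5-fold 46 were called (68.7%), of 67 changed by 2-fold 62 (92.5%), and of 66 changed by 4-fold 66 (100%), with 9 false calls among 183. In 15 comparisons of simulated libraries with no change, at most 1 gene was called.

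The alternatives set out in advance were DESeq2's Wald test, edgeR with DESeq2-style size factors, no filter on low values, the replicate number as a block, a model on the compared groups alone, and leaving out each library in turn. Removal of organelle reads was intended and not run, since no organelle gene is in the tables. For the gene lists, DESeq2-style factors against TMM had been set out in advance as well. The edgeR fit with TMM scaling, the main test of the plan, was run on the recovered reads as an alternative too. After seeing the data, TMM scaling of the normalized values for gene counts and named genes, the FPKM table, a pseudocount of 5, lists of genes changed at least 2-fold by MMS, and counts without the genes of the chromosome segments described for tsk, with p-values readjusted over the remaining genes, were added. Gene lists without XW mock replicate 1, a library that lies apart from its group, a list of histone H2B genes without the members seen first, and a choice of raised genes on part of the libraries were added in the same way. The closing section gives their effect.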

Results

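The series title concerns the recruitment of TONSOKU (TSK), a protein of DNA repair at replication forks, by the N-terminal tails of the histone variants H2A.X and H2A.W. Transcripts were measured in wild type (Col), an H2A.X mutant (h2a.x-1, X), an H2A.W mutant (h2a.w-2, W), the combined mutant (h2a.x/w-2, XW) and a tsk mutant, each as 3 mock and 3 MMS libraries. Depth ranged from 15343687 reads in W MMS replicate 2 to 25115027 reads in Col mock replicate 1, and the next deepest library was XW MMS replicate 1 with 23919904 reads. The labels do not say that replicates came from separate cultures or batches, and if they did not, the p-values measure only the spread between these samples. The first principal component, with 71.4% of the variance, parted MMS from mock libraries, and the following components, with 6.05% and 4.96%, parted genotypes. XW mock replicate 1 lay apart from its group. The chi-square per degree of freedom between its reads and those of replicates 2 and 3 was 17.1 and 18.5, against 2.47 between replicates 2 and 3 and at most 8.28 in any other group.

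**Figure D1:**
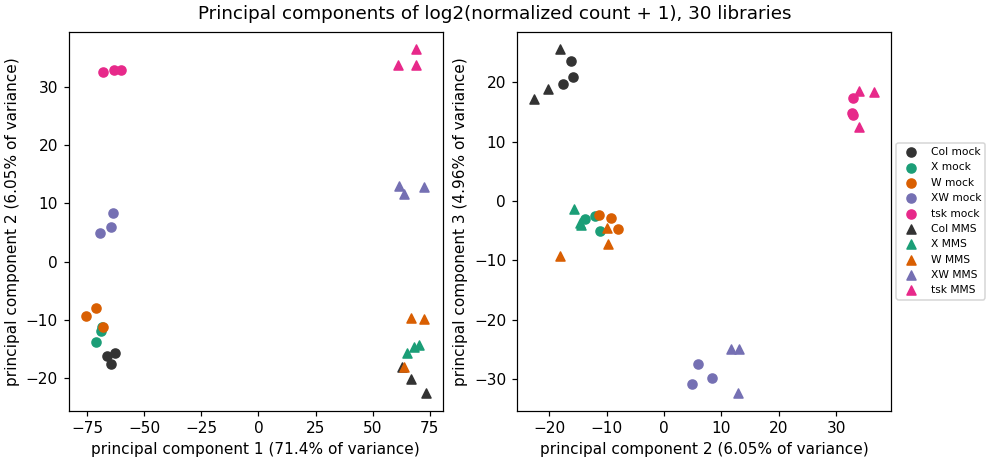
Principal components of log2(normalized count + 1) over 30 libraries, component 1 against 2 on the left and 2 against 3 on the right, each axis giving its percent of variance; each point is a library, circles mock and triangles MMS, coloured by genotype. Component 1 (71.4%) separates the treatments. On component 2 tsk lies highest and XW next, apart from Col, X and W. On component 3 XW lies lowest, tsk lies near Col, and X and W lie between.

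The targeted genes were examined first, because the genotype labels name them. TSK (AT3G18730, chromosome 3, 6445852 to 6453201) stood at 155 ± 7.13 in Col mock and 53.2 ± 7.15 in tsk mock (log2 fold change -1.54, SE 0.14, adjusted p = 2.6e-09), and at 85.6 ± 2.44 and 34.1 ± 8.24 under MMS (-1.33, adjusted p = 3.8e-08). TSK was not called in X, W or XW without MMS and was higher in XW than in Col under MMS (133 ± 14.3, log2 fold change 0.62, adjusted p = 0.0019). HTA5 (AT1G08880, chromosome 1, 2846894 to 2848100), an H2A.X gene, stood at 1040 ± 10.4 in Col mock and 191 ± 19 in X mock (log2 fold change -2.44, SE 0.08, adjusted p = 1.2e-18). In libraries labelled XW it stood at 916 ± 37.2 and was not called (-0.18, adjusted p = 0.1). Under MMS HTA5 was at 910 ± 64.7 in Col, 216 ± 19 in X and 1070 ± 136 in XW. HTA3 (AT1G54690, chromosome 1, 20414316 to 20415287), the other H2A.X gene, was not called in X (514 ± 25.5 against 594 ± 38.2 in Col mock, -0.21, adjusted p = 0.12). It was higher in W mock (1190 ± 27.9, log2 fold change 1.00, adjusted p = 3.9e-10) and in tsk mock (855 ± 0.667, log2 fold change 0.53, adjusted p = 1.4e-05).

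Of the H2A.W genes, HTA6 (AT5G59870, chromosome 5, 24115354 to 24116220) stood at 1140 ± 38.5 in Col mock, 798 ± 35.9 in W mock (log2 fold change -0.52, SE 0.08, adjusted p = 2.9e-05) and 1010 ± 50.6 in XW mock (-0.19, adjusted p = 0.081). HTA7 (AT5G27670, chromosome 5, 9792509 to 9793560) was at 741 ± 51.2 in Col mock, 634 ± 9.66 in W mock (-0.22, adjusted p = 0.25) and 719 ± 224 in XW mock (-0.10, adjusted p = 0.62). HTA12 (AT5G02560, chromosome 5, 575225 to 577216) was higher in W mock (199 ± 6.64 against 144 ± 17.7, log2 fold change 0.48, adjusted p = 0.024) and in XW mock (200 ± 49.4, log2 fold change 0.45, adjusted p = 0.019). The last was 0.26 without XW mock replicate 1 (adjusted p = 0.19), and without any one W library the call in W was lost. The H2B gene AT5G02570 (HTB10, chromosome 5, 576655 to 577176) lies on the other strand within an exon of HTA12 and covers 34.7% of its exon bases, so reads of these genes may be mixed. MMS lowered HTA6 in Col to 353 ± 20.4 (log2 fold change -1.69, adjusted p = 3.6e-17), while it stayed at 922 ± 75.1 in XW, and the difference in response was 1.57 (SE 0.11, adjusted p = 7.3e-11). The labels do not give the kind of allele, so a transcript level near that of Col does not show a functional gene, and these levels do not check the W and XW labels, nor the X label beyond HTA5. Without XW mock replicate 1, the fold change of HTA7 in XW mock was 0.19.

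**Figure D2:**
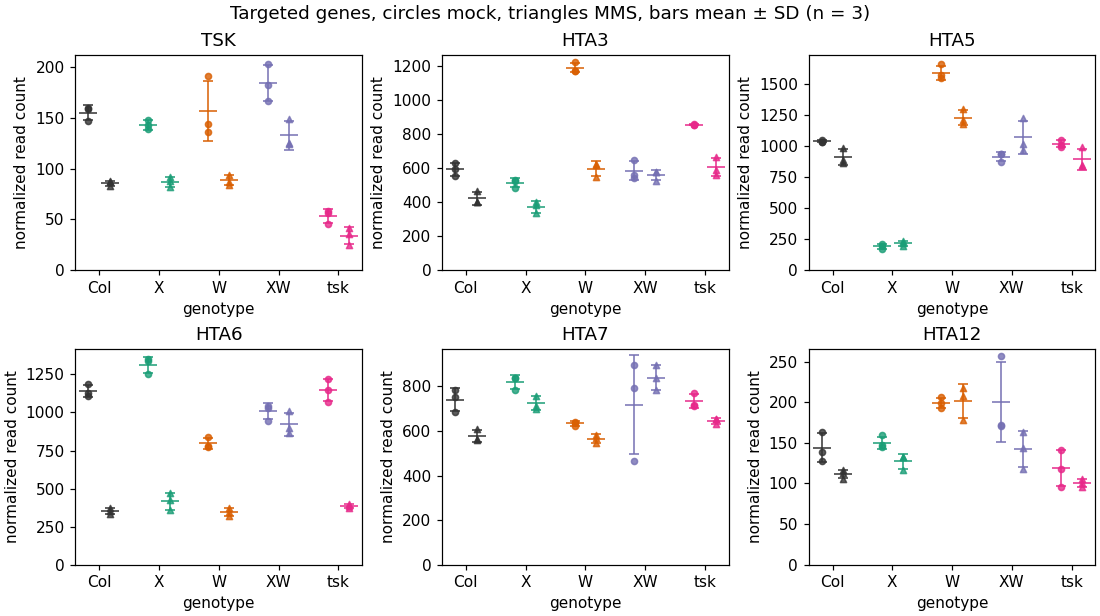
Normalized read counts (vertical axis, from 0) of TSK, HTA3, HTA5, HTA6, HTA7 and HTA12 by genotype (horizontal axis), 3 libraries per group as points, circles mock and triangles MMS, with bars for mean ± SD. TSK is lowest in tsk (53.2 and 34.1), HTA5 in X (191 and 216), and HTA6 under MMS is higher in XW (922) than in Col (353).

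Without MMS, the libraries labelled X were compared with Col to ask what this genotype changes in undamaged seedlings, with the limit that of the H2A.X genes HTA5 was low and HTA3 was not called. In X mock, 868 genes were higher and 648 lower than in Col, 175 and 57 of them by at least 2-fold. AT5G51190, a gene of an AP2/ERF transcription factor that lies wholly under exons of AT5G51180 on the other strand (0.07 in X mock), rose to 322 ± 81.8 from 22.5 ± 6.62 (log2 fold change 3.79, SE 0.22, adjusted p = 2.7e-12). ORA47, of the same family, rose as well (2.93, SE 0.34, adjusted p = 9.3e-07), as did AT1G67105 (3.44). PGAZAT, which encodes a polygalacturonase, fell to 10.7 ± 4.61 from 130 ± 17.8 (-3.57, SE 0.35, adjusted p = 6e-08), and AT1G29090 (-3.17) and the expansin gene EXPA2 (-3.03) fell too. Of 26 measured DNA damage response genes 3 rose, none fell and 23 were not called, with 10 higher when adjusted over the list alone. The 3 were SMR4, a cell cycle inhibitor (log2 fold change 1.55, SE 0.30, adjusted p = 0.0012), XRI1 (0.49) and RAD17, a checkpoint gene (0.42). Of 21 oxidative and xenobiotic stress genes 6 rose and none fell (15 adjusted over the list alone), among them OPR2 (0.74), OPR1 (0.83) and CYP81D8 (1.24). Anthocyanin genes (5 of 7 higher, TT7 0.58, FLS1 0.70 and F3H 0.58) and other H2A genes (4 of 7 higher, HTA2 0.44, HTA1 0.39 and HTA13 0.41) rose as well. In camera these lists were raised (adjusted p = 0.00012 for DNA damage, 5.4e-08 for oxidative, 1.2e-05 for anthocyanin and 0.00019 for other H2A), and with an estimated correlation no call held (adjusted p = 0.16, 0.16, 0.1 and 0.1). Touch and wound genes, a list written after the data were seen, had a median of 0.97 here. The G2/M list was raised by camera with no single call (median 0.23, adjusted p = 0.00012, and adjusted p = 0.33 with an estimated correlation). The count of 1516 rests on the model: it was 3177 with the compared groups alone and 779 without Col mock replicate 1, 780 without X mock replicate 3, 941 without X mock replicate 1 or 2 and 962 without Col mock replicate 2.

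The comparison of W with Col asks the same of the label for H2A.W, a variant of heterochromatin, with the limit that HTA6 alone of its genes was called lower. In W mock 1226 genes rose and 1435 fell, 200 and 68 of them by at least 2-fold. AT5G51190 was again the largest rise (348 ± 66.3 against 22.5 ± 6.62, log2 fold change 3.91, SE 0.22, adjusted p = 5.7e-13), followed by AT5G45630 (3.84) and AT3G01345 (3.71). AT5G56370, an F-box gene, fell most (-3.35, adjusted p = 1.3e-11), then FLC, the repressor of flowering (29 ± 7.85 against 154 ± 7.31, -2.40, SE 0.25, adjusted p = 6.4e-08), and FLP1 (-2.11). Of 26 DNA damage response genes 16 rose, none fell and 10 were not called (18 higher adjusted over the list alone, median 0.46, camera adjusted p = 2.1e-13). Its smallest p-values belonged to GMI1, a gene of recombination after double-strand breaks (log2 fold change 1.11, SE 0.11, adjusted p = 1.8e-08), NAC044, a transcription factor of the damage checkpoint (2.05, SE 0.22, adjusted p = 9.2e-08), and RAD17 (0.88, SE 0.11, adjusted p = 9.2e-07). S phase genes (8 of 27 higher, 13 adjusted over the list alone, camera adjusted p = 3.2e-08) included the replicative histone H3 genes HTR9 (0.75) and HTR1 (0.52) and the ribonucleotide reductase gene RNR1 (0.33). Of 26 G2/M genes 12 rose (16 adjusted over the list alone; CYCB2-2 0.65, IMK2 0.56, CDKB2-1 0.37; camera adjusted p = 9.4e-08, and adjusted p = 0.11 with an estimated correlation). Other H2A genes had 4 of 7 higher and 1 lower (HTA2 1.03, HTA13 0.90, HTA1 0.45, camera adjusted p = 1.5e-05), and anthocyanin genes 5 of 7 higher (FLS1 0.73, CHI 0.51, TT19 1.18, adjusted p = 4.1e-05, and adjusted p = 0.072 with an estimated correlation). Oxidative stress (5 of 21 higher, 1 lower) and heat shock genes (2 of 15 higher) were raised by camera (adjusted p = 0.018 and 0.0016) and not with an estimated correlation (adjusted p = 0.57 and 0.32). ROS1 and IBM1, both regulators of DNA methylation and the 2 measured silencing reporters, fell (-0.69, adjusted p = 0.00031, and -0.41, adjusted p = 0.0031). The touch and wound list had a median of 0.96 in W mock. The count of 2661 fell to 1740 without Col mock replicate 1, and with FPKM values 1529 genes rose and 1141 fell.

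The libraries labelled XW were compared with Col to ask what the combined genotype changes, with the limit that none of the H2A.X and H2A.W transcripts was called lower in XW mock than in Col, so loss of both variants rests on the labels and is not shown by the transcripts. In XW mock 2393 genes rose and 2726 fell, 597 and 92 of them by at least 2-fold. The largest rises were AT5G07610, an F-box gene (108 ± 21.9 against 1.39 ± 0.849, log2 fold change 5.56, SE 0.40, adjusted p = 1.2e-11), AT5G51190 (960 ± 155, 5.38, SE 0.22, adjusted p = 1.2e-16) and AT5G42530 (4.73). Next came ORA47 (251 ± 40.4 against 10.2 ± 5.41, 4.58, adjusted p = 2e-11) and AT3G22235 (4.55). PGAZAT (10.9 ± 5.65 against 130 ± 17.8, -3.55, SE 0.35, adjusted p = 8.9e-09), AT1G29090 (-2.91), FLP1 (-2.71), EXPA2 (-2.67) and DIN2 (-2.51) fell most. DNA damage response genes rose in 21 of 26, with none lower (22 adjusted over the list alone, median 1.08, camera adjusted p = 1.9e-22). They were led by TSO2, a subunit of ribonucleotide reductase (log2 fold change 1.38, SE 0.07, adjusted p = 2.1e-15), GMI1 (1.99, SE 0.11, adjusted p = 1.4e-14) and XRI1 (1.74, SE 0.10, adjusted p = 6.3e-14). Of 11 salicylic acid and immune genes 8 rose and none fell (9 adjusted over the list alone, median 0.89, camera adjusted p = 2.6e-09). Among them were the transcription factor gene WRKY70 (3.99, adjusted p = 5.3e-17), SARD1, an activator of salicylic acid synthesis (3.92, adjusted p = 1.1e-09), and ACD6 (1.66). Other H2A genes had 5 of 7 higher and 1 lower (HTA2 1.38, HTA1 1.02, camera adjusted p = 2.7e-05). S phase (6 of 27 higher, HTR1 0.83, HTR9 0.88, HTR2 0.59) and G2/M genes (8 of 26 higher) were raised by camera (adjusted p = 0.0011 and 0.00068), and not with an estimated correlation (adjusted p = 0.22 and 0.54). ROS1 and IBM1 were again both lower (median -0.40). On lists written after the data were seen, touch and wound genes had a median of 2.03 and seed storage and oil body genes 1.16. Without XW mock replicate 1 the count of 5119 was 4129, of which 3469 were called in the same direction with it, and 21 of 26 DNA damage response genes and 9 of 11 salicylic acid genes were higher. With the compared groups alone the count was 3038, split into 1772 higher and 1266 lower.

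The tsk mutant asks what loss of the repair factor itself does. In tsk mock 2199 genes rose and 3058 fell, 453 and 116 of them by at least 2-fold. A measured fact stands beside every tsk count: 6 chromosome segments, 1408 kb with 269 tested genes, had raised running medians in tsk, and 248 of these genes rose, none fell, and they make 84 of the 453 rises of at least 2-fold. With these genes left out and p-values readjusted over the others, 1925 rose and 3028 fell. Seed storage and oil body genes, a list written after the data were seen, had a median of 1.71 in tsk mock. The largest rises were AT5G07610 (82.5 ± 3.42, log2 fold change 5.19), AT2G18193, an AAA-type ATPase gene (985 ± 76.8 against 47.2 ± 9.84, 4.37, adjusted p = 3e-16) and AT5G60250 (4.27, adjusted p = 2.3e-16). AT4G22960 (4.18) followed, and HISN6B, a gene of histidine synthesis (127 ± 2.43 against 6.85 ± 3.12, 4.11, adjusted p = 1.1e-05). FRO5 (-2.25), PGAZAT (-2.24), EXPA2 (-2.22), AT1G76530 (-2.16) and AT4G19190 (-2.15, SE 0.10, adjusted p = 2.2e-15) fell most. The DNA damage response list had 22 of 26 genes higher and none lower (22 adjusted over the list alone, median 1.28, camera adjusted p = 1.2e-28). TSO2 (1.5, SE 0.07, adjusted p = 1.1e-15), XRI1 (2.01, SE 0.10, adjusted p = 4.8e-15) and GMI1 (2.09, SE 0.11, adjusted p = 7.1e-15) had the smallest p-values, and 1 member, TEB, lies in a segment. Of 26 G2/M genes 9 rose (CDKB1-1 1.53, which lies in a segment, and CYCB2-1 1.12; camera adjusted p = 4.1e-06, and adjusted p = 0.55 with an estimated correlation). Salicylic acid genes had 5 of 11 higher and 1 lower (WRKY70 1.18, SARD1 1.75, and PAD4 0.91, which lies in a segment; adjusted p = 0.11). Meristem genes had 4 of 14 higher and 2 lower (STM 0.86, CLV1 -0.34, and SCR 0.67, which lies in a segment; adjusted p = 0.16). Of the other H2A genes 2 of 7 were higher and 1 lower (HTA11 0.91, in a segment; adjusted p = 0.29). S phase genes had 3 of 27 higher (adjusted p = 0.66), oxidative stress genes 2 of 21 higher and 11 lower (adjusted p = 0.11), and leaf photosynthesis genes 1 of 24 higher and 4 lower (median -0.17, adjusted p = 0.021, and adjusted p = 0.63 with an estimated correlation). With FPKM values 3196 genes rose and 1446 fell, while with TMM scaling 2171 rose and 3139 fell. Why the FPKM split turned was not tested.

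**Figure D3:**
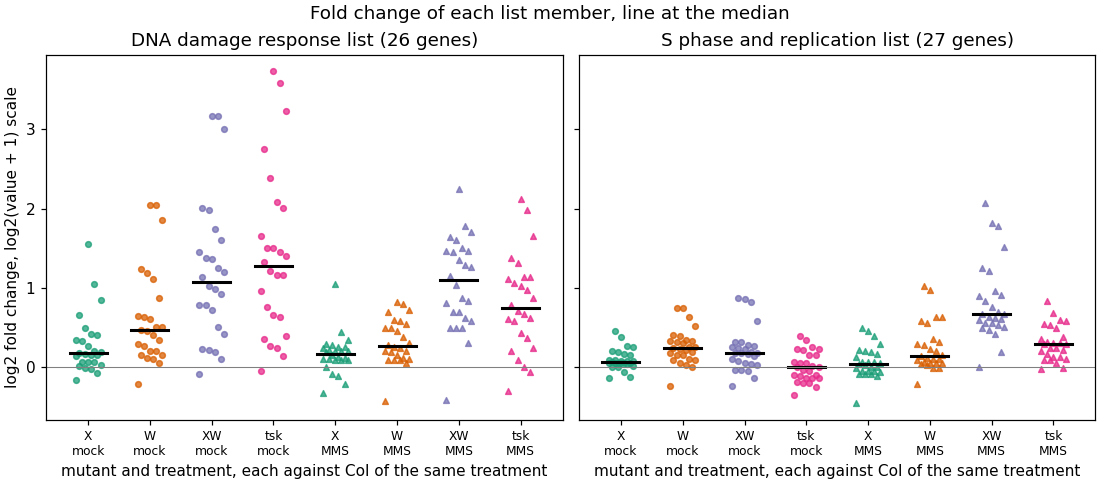
Log2 fold change against Col of the same treatment (vertical axis, log2(value + 1) scale) of each member of the DNA damage response list (left, 26 genes) and the S phase and replication list (right, 27 genes), by mutant and treatment (horizontal axis); points are genes, circles mock and triangles MMS, and lines are medians. The DNA damage medians reach 1.08 in XW mock and 1.28 in tsk mock, and the S phase median is highest in XW under MMS (0.67).

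XW and tsk were then set side by side, since the title joins the variants with TSK. Without MMS 768 genes were higher and 1013 lower in both mutants than in Col, and 265 were called in opposite directions. Independent calls would give 260 and 412. Simulated mutants with no effect and the same Col libraries gave a mean of 0. That value was fixed by the setting, since mutants with no effect have hardly any calls to share. It does not measure what the shared control adds to mutants with many calls. The correlation of fold changes across genes was 0.49, where the shared control alone gave 0.5 in the simulation. Their covariance was 0.0885 against 0.0153, a difference of 0.0732. With only 3 Col libraries the control could not be divided between the mutants, so part of the excess may come from it. The shared rises with the largest smaller change were AT5G07610, AT5G60250 (log2 fold change 4.08 in XW and 4.27 in tsk), AT4G22960 (3.96 and 4.18), AT5G35660 (3.55 and 3.55) and AT2G18193 (3.51 and 4.37), and the shared falls were PGAZAT, EXPA2, FLP1, DIN2 and CCOAMT. Under MMS 1032 were higher and 1270 lower in both (331 and 445 if independent), 216 were opposite, and the covariance was 0.117 against 0.0151, a difference of 0.101. All 4 mutants shared 183 rises and 123 falls without MMS (0.674 and 0.933 if independent) and 244 and 147 with it (1.65 and 0.786), and X and W shared 400 and 287 without MMS (53 and 46 if independent). These counts rest on the same Col libraries too, so part of their excess may come from the shared control.

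Compared directly, 3403 genes were higher and 2618 lower in XW mock than in tsk mock, and 3323 and 2370 under MMS. Histone H2B genes AT5G02570 (log2 fold change 4.27) and AT3G53650 (3.93, adjusted p = 2.7e-17), AT5G24240 (3.92) and DIC2 (3.61) were among the largest rises. HISN6B (-4.85), AT4G19191 (-3.68), FLC (-3.20, 30.4 against 284) and VIM5, a gene of DNA methylation (-2.97), were among the largest falls. Under MMS AT5G24240 (5.68), AT5G02570 (5.53, with the limit that it lies within HTA12) and AT3G53650 (5.25) were highest, and HISN6B (-4.54), AT4G19191 (-4.35) and VIM5 (-3.66) lowest. S phase genes were higher in XW under MMS in 19 of 27, with none lower (median 0.45, camera adjusted p = 1.8e-09), as were 5 of 7 other H2A genes, with 1 lower (HTA2 1.86, HTA13 1.77, HTA10 1.24, adjusted p = 1.9e-06). Of 26 DNA damage response genes 2 were higher and 6 lower in mock (adjusted p = 0.029, and adjusted p = 0.5 with an estimated correlation). Under MMS 9 were higher and 2 lower (adjusted p = 0.032, and adjusted p = 0.3 with an estimated correlation). Salicylic acid genes were higher in XW mock in 8 of 11, with none lower (adjusted p = 5.7e-05, and adjusted p = 0.24 with an estimated correlation). So were 14 of 18 touch and wound genes (median 1.67, p = 0.0037 with an estimated correlation). That list was written after such genes were seen high in XW mock. Under MMS oxidative stress genes were higher in 18 of 21, with 1 lower (median 0.74, adjusted p = 1.5e-07, and adjusted p = 0.16 with an estimated correlation). With the segment genes of tsk left out and p-values readjusted, the splits were 3375 higher and 2352 lower in mock and 3302 and 2118 under MMS. Without XW mock replicate 1 the DNA damage response call in mock was lost (adjusted p = 0.083). The mock count of 6021 was 4848 without XW mock replicate 1 and 3979 with the compared groups alone, and with FPKM values the splits turned to 2400 higher and 4018 lower in mock and 2105 and 3730 under MMS.

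MMS against mock in Col asks what the alkylating agent does to wild type. In Col 7187 genes rose and 7221 fell, 1332 and 2808 of them by at least 2-fold, and the groups did not overlap in 75.3% of tested genes (10% by chance). The largest rises were ELI3-2 (619 ± 452 against 5.29 ± 4.16, log2 fold change 6.61), the mitochondrial small heat shock gene HSP23.6-MITO (377 ± 113 against 3.08 ± 0.672, 6.50, SE 0.39, adjusted p = 1.1e-14) and AT2G38240 (2030 ± 107 against 44.9 ± 38, 6.17). They were followed by HSP17.6A (5.72, adjusted p = 2.1e-15) and RAP2.6, an ERF transcription factor of stress (3300 ± 163 against 68.4 ± 23.7, 5.63, SE 0.25, adjusted p = 1.7e-17). The largest falls were AT1G60590 (9.43 ± 2.85 against 712 ± 47.5, -6.13), AT1G10640 (-5.62), AT5G46890 (-5.58), ST4B (-5.46) and AT4G11210 (-5.27). Of 27 S phase genes 25 fell and 1 rose (median -1.14, camera adjusted p = 1.5e-08), led by HTR2 (-1.81, adjusted p = 3.7e-17), HTR9 (-1.89) and MCM7, a subunit of the replicative helicase (-1.33). Leaf photosynthesis genes fell in 24 of 24 (PSBO2 -1.68, RBCS1B -1.90, CA1 -1.63; median -1.28, adjusted p = 2.7e-11) and G2/M genes in 23 of 26 (median -1.03, adjusted p = 2.6e-06). Falls were also called for meristem genes in 10 of 14 (CLV1 -0.79, KNAT1 -0.82; adjusted p = 0.0034), for anthocyanin genes in 7 of 7 (median -0.97, adjusted p = 0.013) and for other H2A genes in 5 of 7 (HTA11 -1.37, HTA2 -0.78, HTA10 -0.69; adjusted p = 0.034). No member of these 5 lists rose. Oxidative and xenobiotic stress genes rose in 17 of 21 with none lower (UGT74E2 5.23, adjusted p = 7.4e-17, GSTF8 2.04, OPR1 2.97; median 2.23, adjusted p = 2.4e-07). Heat shock genes rose in 14 of 15 with none lower (BZIP60 1.79, adjusted p = 4.2e-19, HSP90.1 2.99, HSP101 3.05; median 2.99, adjusted p = 2.4e-07). With an estimated correlation the S phase call held and the others did not (adjusted p = 0.11 for photosynthesis, 0.16 for G2/M, 0.11 for meristem, 0.23 for anthocyanin, 0.23 for other H2A, 0.16 for oxidative and 0.11 for heat shock).

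Repair genes went both ways under MMS in Col. Of 26 DNA damage response genes 11 rose and 8 fell (median 0.20, adjusted p = 0.32). AGO2 rose by 1.14 (adjusted p = 1.8e-13) and XRI1 by 0.95 (adjusted p = 1.3e-09), and BARD1, a partner of BRCA1, fell (-1.33, adjusted p = 1e-10). Homologous recombination and fork repair genes had 7 of 24 higher and 8 lower (adjusted p = 0.59), and base excision and alkylation repair genes 4 of 13 higher and 2 lower (adjusted p = 0.66). Root markers had 2 of 15 higher and 8 lower (adjusted p = 0.21), and circadian clock genes 4 of 9 higher and 3 lower (adjusted p = 0.49). In the mutants without MMS, between 0 and 3 of the 24 recombination genes were called in X, W and tsk, and 4 in XW. TSK fell by 0.85 (adjusted p = 6.1e-06) and HTA3 fell by 0.49 (adjusted p = 3.3e-06).

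The mutants answered MMS much as Col did, with 14813 genes called in X, 14772 in W, 14518 in XW and 14401 in tsk. In all 5 genotypes 5274 genes rose and 5377 fell. Fold changes across genes correlated with those of Col at 0.94 in X, 0.93 in W, 0.90 in XW and 0.93 in tsk, over genes that are not independent replicates. The largest rises were AT2G38240 in X (7.12) and W (7.39), HSP17.6A in XW (6.91) and RAP2.6 in tsk (6.42). Falls included EXPA8 in X (-6.19), EXPB1 in W (-5.71), AT1G60590 in XW (-6.10) and CYP79F1 in tsk (-5.18). Photosynthesis genes fell in 24 of 24 in each mutant, with medians of -1.12 in X, -0.85 in W, -1.04 in XW and -1.13 in tsk. Heat shock genes rose in 13 of 15 in X and 14 in W, XW and tsk (medians 3.20, 3.32, 2.71 and 3.02). S phase genes fell in 26 of 27 in X (median -1.14), 25 in W (-1.19), 21 in XW (-0.63) and 25 in tsk (-0.81). Camera gave adjusted p = 1.3e-08, 2.4e-08, 0.00066 and 1.7e-06 for these, and with an estimated correlation adjusted p = 0.16 in XW and 0.12 in tsk. For photosynthesis and heat shock no call held with an estimated correlation (adjusted p = 0.15 for both in X, 0.19 and 0.15 in W, 0.16 for both in XW and 0.12 for both in tsk). MMS raised 10 of 26 DNA damage response genes and lowered 5 in X, 10 and 9 in W, 8 and 2 in XW, and 3 and 9 in tsk (median in tsk -0.25, adjusted p = 0.18).

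Whether the response itself differed was tested with the interaction term. In X 403 genes differed from Col, in W 1421, in XW 1806 (780 upward and 1026 downward) and in tsk 505. Without XW mock replicate 1 the XW count was 1660, and the list calls for homologous recombination, anthocyanin and circadian clock genes in XW were lost (adjusted p = 0.39, 0.087 and 0.1), as they were with an estimated correlation and all libraries (0.49, 0.49 and 0.28). LEA7, a late embryogenesis gene, and AT1G04560 fell with MMS in every genotype (-4.51 and -4.13 in Col) and fell less in X (log2 difference 2.46 and 2.32), W (2.98 and 2.61), XW (3.79 and 3.25) and tsk (2.62 and 2.44). On log2(FPKM + 1), a scale where the added 1 weighs more for genes with few reads, AT1G04560 came to -0.34 in X, -0.06 in W and -0.38 in tsk. FLP1 also responded more upward in W (3.23), XW (3.26) and tsk (2.97). AT5G51190 and ORA47, which were already high in the mutants without MMS, responded more downward in X (-3.56 and -2.78), W (-3.40 and -2.83) and XW (-4.34 and -4.54). They were followed in XW by STZ (-3.58), CAF1a (-3.55) and DIC2 (-3.47). The touch and wound list moved along in XW, with 13 of 18 downward and none upward (median -1.61, p = 0.0014 with an estimated correlation), and in X with 7 downward (-0.68, p = 0.045). It was written after such genes were seen high in X, W and XW mock, and the term subtracts these libraries. A downward term was thus favoured in advance, and its p-values are no separate test. Under MMS the list was still higher in XW than in Col (median 0.53, 13 of 18 higher and none lower). In tsk AT2G18193 (-3.71), OLEO4 (-2.95) and SMR7, a cell cycle inhibitor (-2.52, SE 0.43, adjusted p = 0.0014), responded more downward. S phase genes fell less in XW than in Col, with 15 of 27 called upward, none downward and 12 not called (21 adjusted over the list alone, median 0.60, camera adjusted p = 5.6e-17). The most marked were HTR1 (0.99, adjusted p = 1.1e-07), HTR9 (1.19, adjusted p = 3.4e-07) and HTR2 (0.93). In tsk the same list had 1 gene upward, MCM5 (0.41, adjusted p = 0.03), and 8 adjusted over the list alone (median 0.32, camera adjusted p = 4e-08).

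The response of the DNA damage response list to MMS was more downward in tsk than in Col. The list lay above Col in tsk with both treatments. Its median over Col was 1.17 to 1.37 in the tsk mock libraries, which the term subtracts, and 0.71 to 0.8 in those with MMS. In the tsk term 8 of 26 genes were called downward and none upward (13 adjusted over the list alone, median -0.43, camera adjusted p = 4.9e-11). Among them were XRI1 (-1.22, adjusted p = 1.3e-05), BRCA1 (-1.25, adjusted p = 9.4e-05) and NAC044 (-2.09, adjusted p = 0.00025). In XW 3 were upward and 6 downward (XRI1 -0.91, NAC044 -1.23, BRCA1 -0.66; adjusted p = 0.53). In W none was upward and 4 downward (median -0.14, adjusted p = 0.0069, and adjusted p = 0.56 with an estimated correlation). Photosynthesis genes fell less in W, with 11 of 24 upward (19 adjusted over the list alone; RBCS2B 0.62, LHCA2 0.54, LHCB5 0.65; adjusted p = 2.1e-12, and adjusted p = 0.34 with an estimated correlation). In XW other H2A genes (3 of 7 upward, HTA13 0.79, HTA2 0.67, HTA10 0.58, adjusted p = 5e-04), recombination genes (4 of 24 upward, adjusted p = 0.036) and clock genes (2 of 9 downward, adjusted p = 0.024) lost their calls with an estimated correlation (adjusted p = 0.11, 0.49 and 0.28). The count in X was 823 with the compared groups alone, 215 without X MMS replicate 3, 247 without Col mock replicate 3, 249 without Col mock replicate 2, 253 without X MMS replicate 2 and 256 without X mock replicate 3. With FPKM values the splits turned from 219 upward and 184 downward to 147 and 294 in X, and from 891 and 530 to 611 and 885 in W. In XW the count was 1197 with the compared groups alone. In tsk it was 311 without tsk mock replicate 3, 314 without Col mock replicate 2, 322 without tsk MMS replicate 1 and 336 without Col MMS replicate 2, and the split of 277 upward and 228 downward was 366 and 176 under TMM scaling and 244 and 279 with FPKM values.

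Under MMS, X differed from Col in 1309 genes upward and 911 downward, and W in 1569 and 796. In X LEA7 (97.3 ± 43 against 3.7 ± 2.47, log2 fold change 4.46, adjusted p = 5.6e-11), ECP63 (4.44) and AT1G04560 (4.31) were highest. AT5G46960 (-4.39) and PGAZAT (-3.35) were lowest. In W AT1G04560 (3.94), LEA7 (3.86) and AT1G64795 (3.73) were highest, and AT5G56370 (-2.70), FLC (-2.61) and HEI10, a gene of meiotic crossover (-2.28), lowest. Of 26 DNA damage response genes 2 were higher in X (1 adjusted over the list alone, camera adjusted p = 0.041, and adjusted p = 0.68 with an estimated correlation). In W 8 were higher and 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 7.4e-06, and adjusted p = 0.065 with an estimated correlation). Also higher in W were 14 of 26 G2/M genes (adjusted p = 1.3e-10), 17 of 24 photosynthesis genes (adjusted p = 2.2e-13), 7 of 27 S phase genes (adjusted p = 6.1e-05) and 9 of 15 heat shock genes (HSP101 1.35, HSP17.4 1.81, HSP17.6A 1.77; adjusted p = 0.00017), with none lower. These calls were lost with an estimated correlation (adjusted p = 0.065 for the first 3 and 0.2 for heat shock). Other H2A genes were higher in 5 of 7 in W (HTA13 1.17, HTA2 0.89, HTA1 0.34, adjusted p = 1.8e-07). In X photosynthesis genes had 14 of 24 higher and 3 lower (adjusted p = 1.8e-07, and adjusted p = 0.47 with an estimated correlation). The X count of 2220 was 1283 without X MMS replicate 3, 1309 without Col MMS replicate 3 and 1440 without Col MMS replicate 1, and the W count of 2365 was 1429 with the compared groups alone. The seed storage and oil body list had a median of 0.73 in X (p = 0.029 with an estimated correlation), and the touch and wound list 0.65 in W (p = 0.026). With FPKM values the splits were 970 and 1439 in X and 1211 and 1348 in W.

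In XW under MMS 2591 genes were higher and 2541 lower than in Col, 621 and 165 of them by at least 2-fold. AT3G53650 (1420 ± 39.5 against 29.5 ± 6.74, log2 fold change 5.56, SE 0.15, adjusted p = 3.5e-21) and AT5G02570 (5.29, within HTA12), both histone H2B genes, AT1G04560 (5.06) and LEA7 (5.05) were highest. PGAZAT (-4.15), AT5G46960 (-3.89) and CP1 (-3.13) were lowest. Of 26 DNA damage response genes 24 were higher and 1 lower (25 and 1 adjusted over the list alone, median 1.09, camera adjusted p = 9.6e-22). First stood TSO2 (1.71, adjusted p = 1.7e-17), GMI1 (1.47) and PARP2, a sensor of DNA breaks (1.46). S phase genes were higher in 24 of 27 and lower in none (25 adjusted over the list alone, median 0.67, camera adjusted p = 1.7e-23), with HTR1 (1.82, adjusted p = 2.5e-17), HTR9 (2.07) and HTR2 (1.52) in front. Salicylic acid genes were higher in 9 of 11 (WRKY70 2.70, ACD6 2.1, SID2 1.34; median 1.34, camera adjusted p = 6.8e-10). Other H2A genes were higher in 6 of 7 with 1 lower (HTA2 2.05, adjusted p = 1.5e-18, HTA13 1.80; adjusted p = 3.1e-09), G2/M genes in 11 of 26 with none lower (adjusted p = 4.2e-06, and adjusted p = 0.2 with an estimated correlation). Photosynthesis genes were higher in 10 of 24 with none lower (adjusted p = 5.1e-05, and adjusted p = 0.36 with an estimated correlation). Seed storage and oil body genes moved along in 5 of 6 (median 2.48, p = 0.0044 with an estimated correlation), and touch and wound genes had a median of 0.53.

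In tsk under MMS 2584 genes were higher and 3544 lower, 504 and 190 of them by at least 2-fold. Of the 269 segment genes 246 were higher and 1 lower, and they make 96 of the 504. VIM5 (5.16, adjusted p = 1.2e-11), AT4G19191 (5.03, adjusted p = 1.5e-14), AT1G04560 (4.76) and LEA7 (4.75) were highest, and PGAZAT (-2.66) and AT4G19190 (-2.25) lowest. The DNA damage response list had 19 of 26 genes higher and none lower (20 adjusted over the list alone, median 0.75, camera adjusted p = 9.6e-14), led by GMI1 (1.66), TSO2 (1.02) and RAD17 (1.38). Seed storage and oil body genes were higher in 6 of 6 (median 2.01, p = 0.0074 with an estimated correlation). S phase genes were higher in 13 of 27 (14 adjusted over the list alone; ICU2, a subunit of DNA polymerase, 0.68, CDC6 0.84, HTR1 0.38; adjusted p = 5.1e-06, and adjusted p = 0.066 with an estimated correlation). Base excision and alkylation repair genes were higher in 5 of 13 (adjusted p = 0.0096, and adjusted p = 0.069 with an estimated correlation). Oxidative stress genes were lower in 15 of 21 and higher in 1 (CAT1 0.81, GSTF8 -1.01, GSTU24 -1.72; median -0.77, adjusted p = 9.2e-06, and adjusted p = 0.24 with an estimated correlation). With the segment genes left out and p-values readjusted, 2320 were higher and 3528 lower, and with FPKM values the split turned to 3583 higher and 2168 lower, with 3011 and 2839 under TMM scaling.

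The non-additive part, XW minus X minus W plus Col, asks whether the effects of X and W add up, provided that XW carries the same alleles as X and W. HTA5 stood at 191 in X mock and 916 in XW mock, and the labels number the H2A.X allele 1 in X and the combined mutant 2 without the kind of lesion, so the counts may hold effects of different alleles as well as departures from additivity. Without MMS 2133 genes departed from additivity (1139 above the sum and 994 below) and under MMS 1661 (631 above and 1030 below). RLP23 (3.68), AT4G04223 (3.55), AT1G35710 (3.48), the cell wall kinase gene WAK1 (3.30, adjusted p = 1.7e-06) and RLP41 (3.06) exceeded the sum most in mock, and KIN1 (-3.50) and AT2G06002 (-3.07) fell most below it. Under MMS WAK1 (4.93, adjusted p = 7.9e-10), XTH26 (4.4) and SARD1 (3.79, adjusted p = 1.3e-05) were highest, and ECP63 (-3.63), AT2G06002 (-3.55), LEA7 (-3.27) and AT1G04560 (-3.19) lowest. Under MMS 7 of 26 DNA damage response genes exceeded the sum with none below (16 adjusted over the list alone, median 0.56, camera adjusted p = 5.1e-13; TSO2 0.95, adjusted p = 1.6e-07, PARP2 0.82, XRI1 0.63). In mock 10 exceeded it with 1 below (TSO2 0.74, GMI1 0.73, PARP2 0.79; adjusted p = 0.00049, and adjusted p = 0.26 with an estimated correlation). S phase genes exceeded it in 15 of 27 under MMS with none below (19 adjusted over the list alone, median 0.52, camera adjusted p = 4.6e-17). Salicylic acid genes exceeded it in 6 of 11 under MMS with none below (8 adjusted over the list alone, median 0.70, camera adjusted p = 8.8e-08; WRKY70 1.92, ACD6 1.72). In mock 8 did (SAG101 1.09, ACD6 1.71, SARD1 2.81; adjusted p = 3e-06, and adjusted p = 0.082 with an estimated correlation). In mock anthocyanin genes fell below the sum in 5 of 7 (median -0.90, adjusted p = 3e-06) and oxidative stress genes in 7 of 21 (14 adjusted over the list alone, median -0.48, adjusted p = 3e-06). Under MMS photosynthesis genes fell below it in 14 of 24 (median -0.40, adjusted p = 1.2e-10). These calls were lost with an estimated correlation (adjusted p = 0.082, 0.3 and 0.14). HTA5 lay 1.64 above the sum in mock (adjusted p = 4e-10) and 1.87 under MMS (adjusted p = 1.6e-11), since it was low in X and not in XW. Without XW mock replicate 1 the mock count was 1804 and the call for S phase genes in mock went from adjusted p = 0.027 to 0.075 (0.33 and 0.47 with an estimated correlation). The mock count was 1403 without X mock replicate 3, and the MMS count 1097 without W MMS replicate 1. With FPKM values the splits turned to 1059 above and 1187 below in mock and 1122 and 664 under MMS. TMM scaling did not give this turn (1338 and 872, and 741 and 929). How far the library totals by which FPKM scales make it was not tested.

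Genes that MMS raised in both X and W (6492) and lowered in both (6591) were examined in untreated XW and tsk, to see whether these mutants resemble treated plants. In XW mock 870 of the raised genes were higher and 974 lower, and of the lowered genes 753 were higher and 848 lower (camera adjusted p = 0.96 for both). In tsk mock the counts were 688 and 1057 (adjusted p = 0.66) and 663 and 1235 (adjusted p = 0.25). For lists limited to changes of at least 2-fold (1304 and 2394 genes), chosen after the data were seen, XW mock had 321 higher and 136 lower of the raised genes (adjusted p = 0.0013, and adjusted p = 0.74 with an estimated correlation). Of the lowered genes 341 were higher and 119 lower (adjusted p = 0.0073, and adjusted p = 0.73 with an estimated correlation). Over all comparisons camera made 129 calls at the preset correlation, of which 24 held with an estimated correlation. These were DNA damage response in W, XW and tsk mock, in XW and tsk under MMS, in the tsk difference in response and in the non-additive part under MMS. S phase held in W mock, in the MMS response of Col, X and W, in XW under MMS, in the XW and tsk differences in response, in XW against tsk under MMS and in the non-additive part under MMS. Salicylic acid held in XW mock, XW under MMS and the non-additive part under MMS, and other H2A genes in W and XW mock, W and XW under MMS and XW against tsk under MMS.

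The tsk segments lie on chromosome 4 (15295138 to 15815025, 103 tested genes of which 101 rose in mock, median log2 fold change 0.94) and on chromosome 3 (19989292 to 20264686, 64 genes, median 0.91; 19383266 to 19520596, 35 genes, 0.99; 16311975 to 16507415, 22 genes, 1.02). Those on chromosome 1 (21122551 to 21339034, 30 genes, 0.51; 21028137 to 21092709, 15 genes, 0.42) had lower medians. Positions are in TAIR10.1. They are runs of at least 10 tested genes in which the running median of 31 genes exceeded 0.5, and X, W and XW had none. Under MMS the median of the chromosome 4 segment was 0.94 as well.

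**Figure D4:**
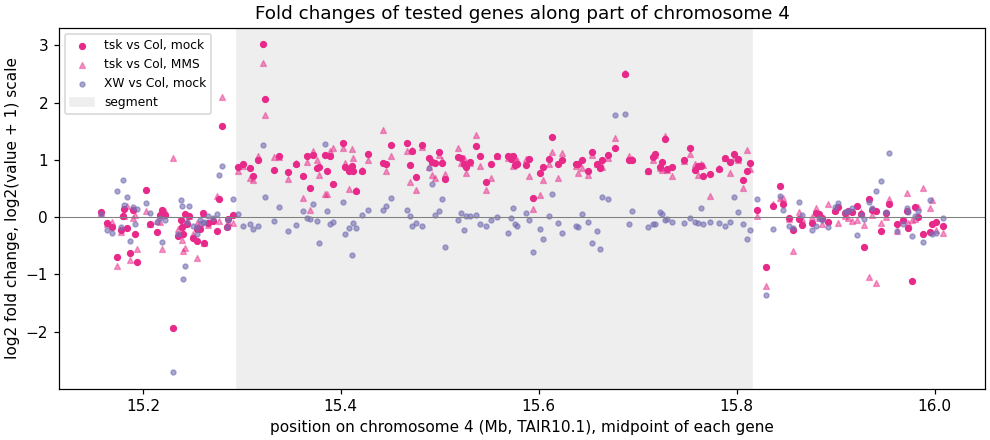
Log2 fold change against Col (vertical axis, log2(value + 1) scale) of tested genes by position in Mb on chromosome 4 of TAIR10.1 (horizontal axis), with the segment shaded; points are genes of tsk without MMS (circles) and with MMS (triangles) and of XW without MMS (small circles). Within the segment tsk genes lie near 0.94 in both treatments, and XW genes do not show the step.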

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

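The test for extra copies, the test of seed RNA in XW and tsk alone, the choice of raised genes on part of the libraries, the list tests without XW mock replicate 1, and the least number of genes for a segment were chosen only after the results they concern had been seen. The lists of touch, seed storage and abscisic acid genes were written after the patterns but before the lists themselves were tested. Of the 18 measured touch genes 6 belong to the 85 genes of the first pattern below, so that list is not independent of the pattern.

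A difference between genotypes in the response to MMS, or a departure from additivity, was the reason to list the following results, each from the test of an interaction term. The response differed from that of Col in 403 genes in X, 1421 in W, 1806 in XW and 505 in tsk, and 2133 genes without MMS and 1661 with it departed from additivity. In W the differences were -0.51 for HTA3 and 0.49 for HTA6. In XW they were 0.60 as the median of the S phase genes, 0.43 for HTA3, 0.41 for HTA5, 1.57 for HTA6 and 0.64 for HTA7. HTA7 stood at 467 in XW mock replicate 1 against 794 and 896 in replicates 2 and 3, so its difference rests in part on that library. In tsk the medians were -0.43 for the DNA damage response genes and 0.32 for the S phase genes. The non-additive part without MMS was -0.82 for HTA3 and 1.64 for HTA5, and under MMS it was 0.56 for DNA damage response, 0.52 for S phase and 0.70 for salicylic acid genes as medians, 1.87 for HTA5, 1.17 for HTA6 and -0.69 for HTA12. The gap of a single library to its group was not tested in groups of 3. XW mock replicate 1 differed from the mean of the other libraries of its group with an SD over genes of 0.344 on the log2 scale, the widest of the 30 libraries, and 288 genes lay at least 2-fold apart, against 341 in X MMS replicate 1.

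Other splits of the same libraries were compared with the real ones. For interaction terms 100 splits were drawn. With the real split counted among them, at least as many genes as in the real split were found in 3 of 100 for the W difference in response (real 1421, highest other 3770). For the non-additive part it was 2 without MMS (2133 and 3971) and 1 with MMS (1661 and 800). In X it was 9 of 100 (403 and 3325), in XW 13 (1806 and 7556) and in tsk 11 (505 and 3931). Splits that exchange genotype labels within a treatment turn the genotype difference into an interaction, and counts several times the real one point to that structure of the samples. Such splits are not free of effects, so these shares cannot decide for or against chance in any of the interaction terms. Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05, and the real split, 1 of 10, gave the most genes in each. The highest other counts were 0 in X, 2 in W, 2 in XW and 1 in tsk for mutants without MMS (real 1516, 2661, 5119 and 5257), and 22, 77, 12 and 2 with MMS (2220, 2365, 5132 and 6128). For MMS against mock they were 26 in XW (14518) and 0 in Col, X, W and tsk (14408, 14813, 14772 and 14401), and for XW against tsk 4 without MMS (6021) and 2 with it (5693).

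A first pattern is a set of 85 genes at least 2-fold higher in X, W and XW than in Col without MMS. A list of 21 touch and wound genes (18 measured), written after genes of this kind had been seen in the set, had a median log2 fold change of 2.03 in XW, 0.97 in X, 0.96 in W and 0.30 in tsk, where 7 were higher and WRKY18 lies in a segment. In XW 16 of 18 were higher (camera p = 1.1e-25, and p = 0.00035 with an estimated correlation). Of the 18, 6 belong to the 85 genes chosen for high values, so these p-values are no separate test. The 12 genes outside the 85 had medians of 1.79 in XW, 0.77 in W and 0.60 in X. MMS against mock in Col raised 15 of the 18 and lowered 2 (median 1.99), so the list is not particular to handling. Handling of the seedlings at harvest may account for part of the set, and the list cannot tell it from the genotypes themselves. Against low chance values in the Col libraries as the whole source speaks that the 85 genes stood a median of 0.87 higher in X, W and XW than in tsk, which has the same Col control, although 55 of the 85 lay above tsk and 64 were called higher in tsk too. The genes were chosen for high values in X, W and XW, which favours that difference, and for genes chosen by the means of 2 libraries of each mutant and measured in the library left out the median was 0.65, 0.66 and 0.76.

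A further pattern is that genes changed at least 2-fold in tsk alike with and without MMS lie close together. Within 2 Mb of TSK there were 15 such genes, and 95% of random placements along the genome gave up to 31, so this test cannot tell. None of the 6 segments described above lies in that window. The nearest starts at 16311975 on chromosome 3, where TSK ends at 6453201, which argues against a segment at the mutated locus for these 6. Elsewhere, up to 26 of 100 neighbouring genes were of this kind, on chromosome 4, against at most 11 in 1000 shuffles, which is consistent with whole segments being changed. In the chromosome 4 segment 94.2% of tested genes had a log2 fold change of 0.5 to 1.5, which does not test an extra copy because segments were searched for by a running median over 0.5, and medians per library ran from 0.92 to 0.96 in tsk and from -0.06 to 0.02 in the other genotypes. An extra copy therefore stays open for this segment, those on chromosome 3 (96.9%, 94.3% and 77.3%) and those on chromosome 1 (53.3% and 13.3%, and 63.3% and 60% under MMS), as do loss of TSK itself and the history of the line, since DNA was not measured here.

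The last pattern is that LEA7, a late embryogenesis gene, and AT1G04560 were higher than in Col in all 4 mutants under MMS, genes singled out for their large changes and not a tested group, of which AT1G04560 was higher in all 4 without MMS too (from 1.34 in W to 2.32 in tsk) and belongs to the 85 genes above, as do ECP63, TIP3;1 and M17. RNA from seeds that germinated late should bring storage and oil body transcripts. The 6 measured of 19 listed genes (CRA1, OLEO5, PAP85, EM6, PER1 and SUS3) had medians of 0.73 in X, 0.14 in W, 2.48 in XW and 2.01 in tsk under MMS. The lowest, 0.14, speaks against such RNA for all 4. Of the 6 only CRA1, PAP85 and OLEO5 encode storage or oil body proteins. These stood at 124, 4.19 and 23.7 in W under MMS, against 137, 8.78 and 24.3 in Col. Without MMS the same list had medians of 1.16 in XW and 1.71 in tsk (p = 0.057 and p = 0.0048 with an estimated correlation), with 4 and 5 of the 6 called higher, so the rise there did not need MMS. In X and W mock the medians were 0.54 and 0.64 (p = 0.14 and p = 0.28 with an estimated correlation), with 2 and 1 called higher. The lower of XW and tsk under MMS, 2.01, leaves late seed RNA as a candidate explanation for these alone, with CRA1, the most abundant of the list in these 2, at 137 in Col, 124 in W, 713 in XW and 631 in tsk. A wider abscisic acid response, judged by 15 of 16 vegetative genes, had medians of 0.46 in X, 0.49 in W, 0.36 in XW and -0.06 in tsk. The last speaks against a rise of the list as a whole in all 4. A wider response, like the genotypes themselves, stays open for X, W and XW. In tsk under MMS 3 members were called higher and 2 lower. RAB18 stood at 862 against 128 in Col and RD29B at 443 against 92.1, while KIN2 stood at 2940 against 4590 and HAB1 at 1590 against 2420. A response of part of the list therefore stays open in tsk as well.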

How the results depend on the processing

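The edgeR fit with TMM scaling was the main test of the plan and served here as an alternative. TMM scaling of the normalized values (set out in advance for the gene lists alone), FPKM values, a pseudocount of 5, lists of genes changed at least 2-fold by MMS, counts without segment genes, and list tests without XW mock replicate 1 were chosen only after the data were seen. Of the named genes, 990 results kept direction and call with DESeq2 and 23 lost the call, and the numbers were 989 and 27 with edgeR and DESeq2-style size factors, 994 and 23 with edgeR and TMM, 1009 and 7 with TMM scaling, 950 and 60 with FPKM values, 956 and 54 with the compared groups alone, 1012 and 5 with a pseudocount of 5, and 1017 and 0 without a filter. With the replicate block 1013 kept and 4 lost the call, and camera made 130 calls against 129, but libraries that share a number were no more alike (mean correlation -0.00622) than others (0.00312). With the compared groups alone counts moved to 3177 (X mock), 3038 (XW mock), 1429 (W under MMS), 823 and 1197 (difference in response of X and XW) and 3979 (XW against tsk mock); the cause was not tested. Over all fits that left out 1 library, 6812 results of named genes kept direction and call, 540 lost the call, 7 gained it and 3 reversed. With an estimated correlation 24 of 129 list calls held. Leaving out a library gave 779 to 1013 genes in X mock, 1740 to 2211 in W mock, 1283 to 2096 in X under MMS, 215 to 597 and 311 to 578 for the difference in response of X and tsk, and 1403 to 2558 and 1097 to 1698 for the non-additive part without and with MMS; the cause was not tested. Without XW mock replicate 1, HTA7 reversed; over the libraries left out it ran from -0.28 to 0.19 (XW against Col, mock), -0.01 to 0.46 (MMS against mock, XW) and -0.27 to 0.20 (XW against tsk, mock). On log2(FPKM + 1) AT1G04560 reversed to -0.34 (X), -0.06 (W) and -0.38 (tsk) in the difference in response. The added 1 weighs more on that scale for genes with few reads, and its part in the reversal was not tested. No setting moved the median of all genes by over 0.1. Removal of organelle genes was not run, for want of such genes. Depth allows no statement on genes without reads in some libraries, which the tables leave out.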

Other observations

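The lists of histone H2B genes and of marks of the single mutants were chosen only after the results had been seen, the first after HTB5, HTB6 and HTB10 stood out, and tests without these 3 were added.

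Histone H2B genes, of which 10 of 11 were measured, were compared over all contrasts, and all 10 were higher in XW than in tsk (median log2 fold change 1.52 without MMS, camera p = 9.8e-22, and p = 9.6e-06 with an estimated correlation). For the remaining 7 genes, without the 3 that stood out, medians without MMS were 1.25 in XW against tsk, 1.04 in XW against Col, 0.64 in W and 0.22 in X. In camera the list of 7 gave p = 3.6e-05, 1.5e-05, 2.1e-05 and 0.011 for these, in the same order, with an estimated correlation. HTB10 (AT5G02570), which these 7 leave out, lies within an exon of HTA12 on the other strand, so its reads may be mixed with those of a targeted gene. Without MMS 10 of 10 rose in XW (median log2 fold change 1.33, camera p = 2.2e-25, and p = 3.2e-06 with an estimated correlation), 10 in W (0.88, p = 4.2e-25 and 3.4e-06) and 6 in X (0.31, p = 5.2e-09 and 0.0019), while in tsk 1 rose and 5 fell (-0.10, p = 0.41). HTB6 (AT3G53650) stood at 58.3 in Col, 147 in X, 564 in W, 1240 in XW and 80.2 in tsk, and HTB11, the more abundant gene, at 1200 in Col and 3190 in XW. MMS lowered 9 of 10 in Col (median -0.85, p = 0.00087, and p = 0.055 with an estimated correlation) and 2 in XW, where 2 rose (-0.13). Under MMS 10 of 10 were higher in XW than in Col (median 2.26, camera p = 2.3e-31, and p = 6.4e-07 with an estimated correlation). In W 10 were higher (0.88), in X 8 (0.49) and in tsk none (0.02). The difference in response was called upward for 7 genes in XW. Over the list, its median was 0.72 (camera p = 6.8e-12, and p = 0.00044 with an estimated correlation), and 9 of 10 exceeded the sum of X and W under MMS (1.03).

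AT4G19190 fell in tsk (-2.15 without MMS and -2.25 with it) where its neighbour in number, AT4G19191, rose (5.03 under MMS), a pair singled out after its values were seen.

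Since HTA5 was low in X and not in XW, genes changed in the single mutants alone were looked up in XW and, as background, in tsk. Of 6 genes that mark X, 16.7% were changed alike in XW and 0% in tsk, and of 5 genes that mark W, 60% and 40%. These numbers are too small to tell which single mutant the XW libraries resemble.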
